A study of Mus musculus with 6 samples.

How the data were processed

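RNA sequencing was analysed from 6 libraries of common myeloid progenitors, the precursors of the erythroid-megakaryocytic and granulocyte-monocyte branches of blood formation. Per the labels' protocols, the cells were sorted from C57BL/6 mouse fetal liver at E13.5 (embryonic day). The gate took cells negative for markers of B cells (B220), T cells (CD3, CD4, CD5 and CD8), granulocytes (Gr-1) and erythroid cells (TER-119) and for CD41 and CD48, negative for Sca-1, low for Fc receptor, and positive for CD34 and c-Kit. RNA was extracted with Trizol and made into libraries with standard Illumina protocols, per the labels. The labels put 3 libraries in the wild-type group (A, F and L) and 3 in the homozygous mutant group (C, D and Q), whose Gata2 -77 enhancer was deleted. The replicate letters differ between the groups, so no samples were paired. The labels do not say whether the libraries come from separate animals, so p-values measure only the spread between these samples.

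The authors' deposited files list 24815 Ensembl gene identifiers per library. The submitters' processing notes name CASAVA 1.8.2, Bowtie 1.1.1, RSEM 1.2.18 and the genome build mm10. The annotation release, read layout and strandedness are not given in the sources used here. Expected counts, the read counts that RSEM assigns to each gene and that need not be whole numbers, were deposited without normalization, per the file headers. The deposited TPM values give transcript abundance corrected for gene length, scaled to the same total in each library, per the file headers. The deposited FPKM values were used only as a sum per library, as a description of transcript length. Gene lengths in bases were taken from the length column, per the file headers, which equals the effective length column in every row. Gene names came from a table keyed on Ensembl identifiers, which named 24448 of the identifiers and left 367 without a name. Positions are those of the GENCODE M21 annotation of the same build, and the authors' annotation release is not known. RSEM can split reads between near-identical genes, so values of the globin paralogs are uncertain, as are those of overlapping or antisense genes.

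Depth ran from 14473913 to 30596279 expected counts per library. Counts were rounded to whole numbers and fitted with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr with its default minimum count of 10, which left 12222 genes. Libraries were scaled by TMM, and mutant was compared with wild type by the quasi-likelihood F test with Benjamini-Hochberg adjustment and a threshold of 0.05. Standard errors are the absolute log2 fold change divided by the square root of F. Values per library are CPM (counts scaled to a common library size) with TMM factors, and means are given with their SD (n = 3 per group). Correlations and principal components used log2 CPM with a prior count of 2. The smallest chi-square per gene between libraries of the same group was 9.25, over genes with at least 10 counts, which is above counting noise and does not show whether the libraries are biological replicates. Each library was counted as 1 sample, as the labels list them.

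Gene lists for blood lineages, pathways, the Gata2 neighbourhood and other cell types (21 in all, including a sex-linked list used as a check) were fixed from general knowledge before the data were examined, as were the design and the settings listed as fixed in advance. For each list, members past the threshold were counted over all genes tested and again adjusted over the list alone. The 20 lists other than the sex-linked list were tested with camera from limma 3.58.1, a competitive test with a preset inter-gene correlation of 0.01, adjusted over the 20 lists. With an estimated correlation in place of the preset value, 2 of the 10 lists past the threshold kept their call, namely the megakaryocyte and mast cell lists. With the preset correlation, camera also put 2 to 10 lists past the threshold when the libraries were split in ways other than by genotype. The test fry was also run, which asks whether a list's genes move one way on balance and does not compare them with other genes. The rule for naming genes took Gata2 and its neighbours and, among genes past the threshold with a mean of at least 50 counts, no overlap of the groups and an informative symbol, the 12 largest rises, the 12 largest falls and the 10 smallest adjusted p. It also took up to 4 members per list with the smallest p, members behind any count of 5 or fewer, all lineage transcription factors, and the 3 most abundant members of each list of another cell type. Rhag, Sptb, Hbb-y, Hba-a1, Hba-a2, Hbb-bs, Hbb-bt, Alb, Afp, Apoa1, Ttr and Mki67 fall outside the rule and were chosen after their values were seen. The position of the deleted enhancer was not used, and the list symbols Hbb-b1, Hbb-b2, Ahsp, Gp49a, Cebpd, Gbp6, Spink3 and Tsix matched no gene in the files. Results for some list members are not reported here.

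The code was tested on simulated counts with the means and sizes of the real libraries and 200 changed genes. With all 6 libraries and 12222 genes, it recovered 1% of 2-fold and 72% of 4-fold changes, with 2 false calls among 75. Without mutant C, on 12614 genes, it recovered 72% and 89%, with 14 false calls among 175. None of 40 unchanged lists and all 10 changed lists were called in either simulation. The simulated genes were drawn independently of each other, whereas the hepatoblast list had an estimated inter-gene correlation of 0.56 in the real libraries. The simulations therefore do not show how often camera calls unchanged lists of correlated genes.

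The settings fixed in advance were other scaling factors, other filters, DESeq2 1.42.0, limma-voom, limma on log2 TPM with pseudocounts of 1 and 0.1, counts not rounded, a gene length offset, removal of hemoglobin, mitochondrial and ribosomal protein genes, an adjusted p under 0.01, a Y-linked covariate, and leaving out each library in turn. After the data were seen, sample quality weights, a ribosomal protein covariate, and the removal of wild type A and mutant C together were added. Counts of list members and the naming rule were also applied to the fit without mutant C, the library that stood apart.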

Results

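Gene expression was measured by RNA sequencing in common myeloid progenitors sorted from mouse fetal liver at E13.5 (embryonic day). Wild-type cells were compared with cells homozygous for a deletion of the Gata2 -77 enhancer, a regulatory element named for its distance upstream of the gene for the transcription factor GATA2. The comparison asks which transcripts of these progenitors depend on the enhancer. There were 3 libraries per genotype. Wild-type libraries A, F and L held 21509720, 14473913 and 15365999 expected counts, and mutant libraries C, D and Q held 14800563, 19155874 and 30596279.

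Mutant C differed from the other libraries. Correlations of log2 CPM across genes ran from 0.974 to 0.989 among the other 5 libraries and from 0.880 to 0.923 between mutant C and each of them. The first principal component held 71.8% of the variance and separated mutant C (score 103) from the rest (-38.8 to -7.02). The second, with 11.7%, placed mutants D and Q at -29.9 and -22.9 and the wild-type libraries between 12.2 and 19.5, with mutant C at 7.17. Ribosomal protein genes took 20.9% of counts in mutant C and 6.38% to 8.69% in the others, and mitochondrial genes 10.1% against 3.54% to 5.80%. The mean gene length weighted by counts was 1781 bases in mutant C and 2834 to 3124 bases in the others. Its ratio to mutants D and Q fell with gene length, with Spearman's rho of -0.75 across 12222 genes, which are not independent replicates. Counts of genes past the threshold over all genes are therefore also given without mutant C.

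**Figure D1:**
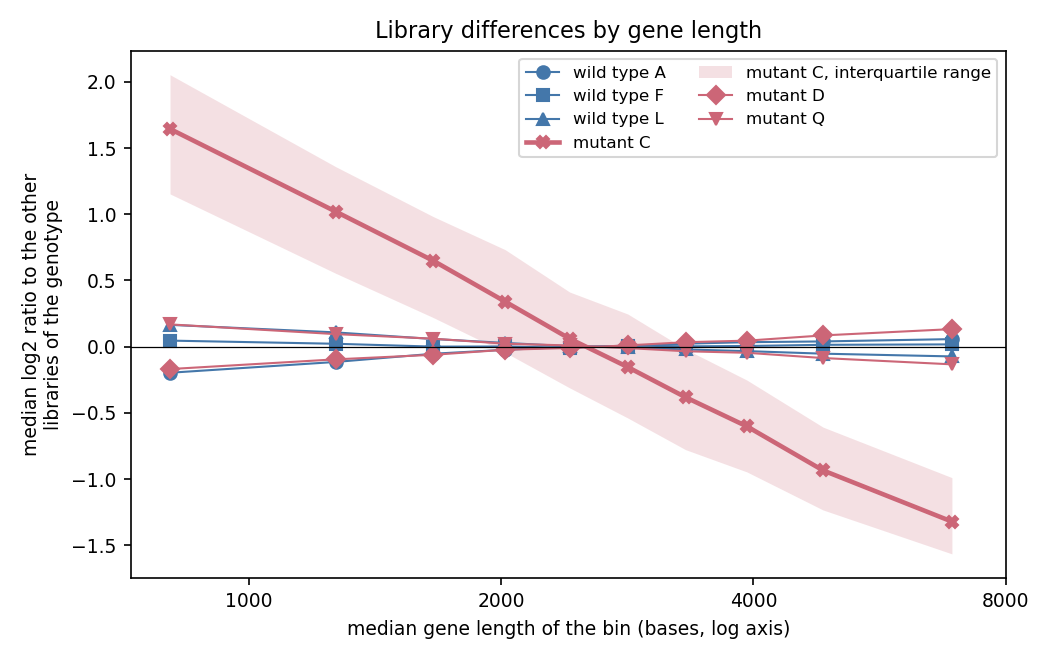
Median log2 ratio of each library to the other libraries of its genotype (vertical axis) in 10 bins of gene length (horizontal axis, bases, log scale); blue is wild type, red is mutant, and the band is the interquartile range for mutant C. Mutant C runs from 1.64 in the bin of shortest genes to -1.32 in the bin of longest genes, and mutants D and Q are each compared with the other alone.

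Gata2 itself was lower in every mutant library than in every wild-type library. Its level was 66.6 ± 10.9 CPM in wild type (78.6, 57.4 and 63.9 in A, F and L) and 14.4 ± 4.80 CPM in the mutant (8.92, 16.5 and 17.8 in C, D and Q). This is 4.59-fold lower, a log2 change of -2.20 with a standard error of 0.30. The deposited TPM values were 53.1, 34.6 and 37.9 in wild type and 1.85, 9.92 and 9.58 in the mutant. The gene (ENSMUSG00000015053) lies on chromosome 6 from 88193891 to 88207032 on the plus strand of mm10. The deletion is outside the transcript, so residual reads do not contradict the genotype labels. The change missed the threshold over all genes by edgeR's quasi-likelihood test (adjusted p = 0.068) and passed it adjusted over the list of lineage transcription factors alone (adjusted p = 0.0045) and without mutant C (log2 change -1.97, adjusted p = 0.0019).

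The genes around Gata2 did not pass the test. Of 18 tested neighbours, 0 were called by edgeR over all genes and 0 adjusted over the list alone, with all 6 libraries, and 0 had an unadjusted p under 0.05 or were called by DESeq2 or limma-voom. Without mutant C, 0 of 19 passed over all genes by edgeR (2 at an unadjusted p under 0.05) and 2 fell adjusted over the list alone, the platelet glycoprotein gene Gp9 and Mgll, which encodes monoacylglycerol lipase, with a mean over the list of -0.19. The median log2 change of the neighbours was -0.05 and their mean 0.10, and the list as a whole did not differ from other genes (camera adjusted p = 0.69). The smallest p among them belonged to 1810044D09Rik, Isy1, Cnbp and Ruvbl1, each at an adjusted p of 0.58. Cnbp, which encodes a nucleic acid binding zinc finger protein, had 846 ± 96.1 CPM in wild type and 1307 ± 669 CPM in the mutant. The SD of Cnbp in the mutant reflects mutant C, with 2080 CPM, beside 903 and 939 CPM in D and Q.

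Most genes past the threshold were lower in the mutant. With all 6 libraries, 19 of 12222 genes passed an adjusted p of 0.05 by edgeR's quasi-likelihood test, of which 18 fell and 1 rose, all by at least 2-fold. Without mutant C, 106 of 12614 genes passed, of which 96 fell and 10 rose, and 79 changed at least 2-fold. All 19 genes of the first set were in the second. With any other library left out, edgeR called 0 genes, while 294 to 1611 genes had an unadjusted p under 0.05 and no other tool was run on those subsets. By DESeq2 on all 6 libraries 124 genes passed, out of 18406 tested without the filter used for edgeR, so the gene sets differ as well as the tools. In 2693 of the tested genes (22.0%) the groups did not overlap, and in 1396 of them every mutant library was the lower. Chance gives 10% for a single gene, but genes of a library vary together, so the share can lie far from 10% without an effect of genotype. The share under other groupings of the libraries was not computed. The median log2 change of all tested genes was -0.02.

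The smallest adjusted p, 0.012, was shared by Samd14, Dach1, Mfsd2b, Muc13 and Mylk3. Samd14, which encodes a sterile alpha motif domain protein, fell from 12.3 ± 2.11 to 0.640 ± 0.123 CPM, 19.9-fold (chromosome 11, 95009879 to 95026087). Mfsd2b, a sphingosine-1-phosphate exporter of red cells and platelets, fell 50.5-fold from 24.3 ± 7.46 CPM (chromosome 12, 4862440 to 4874359). Mylk3, a myosin light chain kinase, fell 21.7-fold, Dach1, a transcriptional cofactor, 8.24-fold, and the transmembrane mucin gene Muc13 7.41-fold from 70.0 ± 11.4 CPM. Ltbp1, which encodes a latent TGF-beta binding protein, went from 5.34 ± 1.24 to 0.0422 ± 0.0488 CPM (adjusted p = 0.021). Slc14a1, the urea transporter of red cells, fell 5.67-fold, and Gna14, a G protein alpha subunit, 5.43-fold. The gene Etl4 went from 4.73 ± 1.86 to 0.125 ± 0.0856 CPM, a log2 change of -5.04, and of -5.99 without mutant Q. The single rise was Socs2, an inhibitor of cytokine receptor signalling, which went from 1.49 ± 0.234 to 10.9 ± 2.62 CPM, a 7.22-fold increase (log2 change 2.85, standard error 0.27, adjusted p = 0.032). Every mutant library lay above every wild-type library for Socs2 (chromosome 10, 95385362 to 95417180).

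Genes of the erythroid lineage were lower in the mutant as a group. Of 34 tested members, 3 fell over all genes, namely the erythropoietin receptor gene Epor, the water channel gene Aqp1 and Hemgn, a nuclear protein gene of blood progenitors. Epor went from 4.94 ± 1.44 to 0.597 ± 0.103 CPM, 8.31-fold, Aqp1 fell 3.32-fold and Hemgn 2.72-fold. Adjusted over the list alone, 16 fell, among them Gata1, Klf1, Rhag and Sptb, and 1 rose, the embryonic globin gene Hbb-y. Without mutant C, 11 of 35 tested members fell over all genes, among them Car1, which went from 5.54 ± 1.53 CPM in wild type to 0.220, 0 and 0 CPM in C, D and Q. The median log2 change was -1.02 and the list was lower than other genes by camera (adjusted p = 2.3e-22), a call lost with an estimated correlation (adjusted p = 0.091) and kept without mutant C (adjusted p = 0.048 with an estimated correlation). The hepatoblast list had a median log2 change of 2.57 between the same groups (camera adjusted p = 1.3e-10, and adjusted p = 0.41 with an estimated correlation). Adult globin transcripts did not pass over all genes by edgeR in either fit, and without mutant C Hba-a1, Hba-a2, Hbb-bs and Hbb-bt fell adjusted over the list alone. Hbb-bs stood at 192 ± 70.8 CPM in wild type, 89.4 and 86.9 in D and Q, and 649 in mutant C. The heme synthesis list of 20 genes had 0 members past the threshold by edgeR (3 at an unadjusted p under 0.05), 0 by DESeq2 and 0 by limma-voom, and a camera adjusted p of 0.12. Without mutant C its adjusted p was 3.5e-06 (0.14 with an estimated correlation), and Steap3, which encodes an iron reductase, fell with a log2 change of -0.51.

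Megakaryocyte and platelet genes were lower in the mutant as a group. Of 23 tested members, 22 had a fitted change below 0, with a median log2 change of -1.46. Over all genes 3 fell: Itga2b, Gp5 and Treml1. Itga2b, which encodes the integrin alpha chain CD41, fell 3.94-fold from 31.4 ± 5.66 to 7.96 ± 0.152 CPM (adjusted p = 0.032). CD41 is among the markers against which the cells were gated in both genotypes. Gp5, a subunit of the platelet von Willebrand factor receptor, went from 3.04 ± 0.621 to 0.104 ± 0.0538 CPM at a mean of 31 counts, and Treml1, a platelet granule receptor, fell 10.8-fold. Adjusted over the list alone 15 members fell, including Vwf (5.88-fold) and the thrombin receptor gene F2r (2.26-fold), and 0 rose. Without mutant C, 12 of 24 members fell over all genes. The list was lower by camera with the preset correlation (adjusted p = 4.3e-24) and with an estimated correlation (adjusted p = 0.0065). Its estimated correlation was -0.037, below the preset 0.01, so the larger p does not come from correlation between genes. The versions of camera therefore differ in more than the correlation, and a call lost with the estimated one need not reflect correlated genes alone. The median of the hepatoblast list was 2.57 between these groups (adjusted p = 0.41 with an estimated correlation).

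Mast cell and basophil genes had the lowest median of the 20 tested lists, -2.03 on the log2 scale. Of 15 tested members, 1 fell over all genes, Slc45a3, which went from 9.13 ± 4.15 to 0.0310 ± 0.0537 CPM, with 0 CPM in mutants C and D. Adjusted over the list alone 9 fell and 0 rose, and without mutant C 9 fell over all genes. Among these 9, Cpa3, the mast cell carboxypeptidase gene, went from 67.9 ± 7.67 to 6.16 ± 4.21 CPM, 11.4-fold lower with all libraries (adjusted p = 0.072) and 18.1-fold without mutant C (adjusted p = 4.8e-05). Hdc, the histamine-synthesizing enzyme gene, was 7.19-fold lower, Il1rl1, the receptor gene for interleukin 33, 17.2-fold and Slc18a2, a monoamine transporter gene, 4.08-fold. The camera adjusted p was 2.6e-17, and adjusted p = 0.030 with an estimated correlation. Between these groups the hepatoblast list had a median of 2.57 (adjusted p = 0.41 with an estimated correlation). Only 3 eosinophil genes were tested, Il5ra, Siglecf and Cebpe. Il5ra was 3.68-fold and Siglecf 1.73-fold lower, both past the threshold adjusted over the list alone and neither over all genes by edgeR (2 at an unadjusted p under 0.05), while DESeq2 called Il5ra and limma-voom 0, and Siglecf fell over all genes without mutant C (list adjusted p = 4.0e-04, and 0.20 with an estimated correlation).

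**Figure D2:**
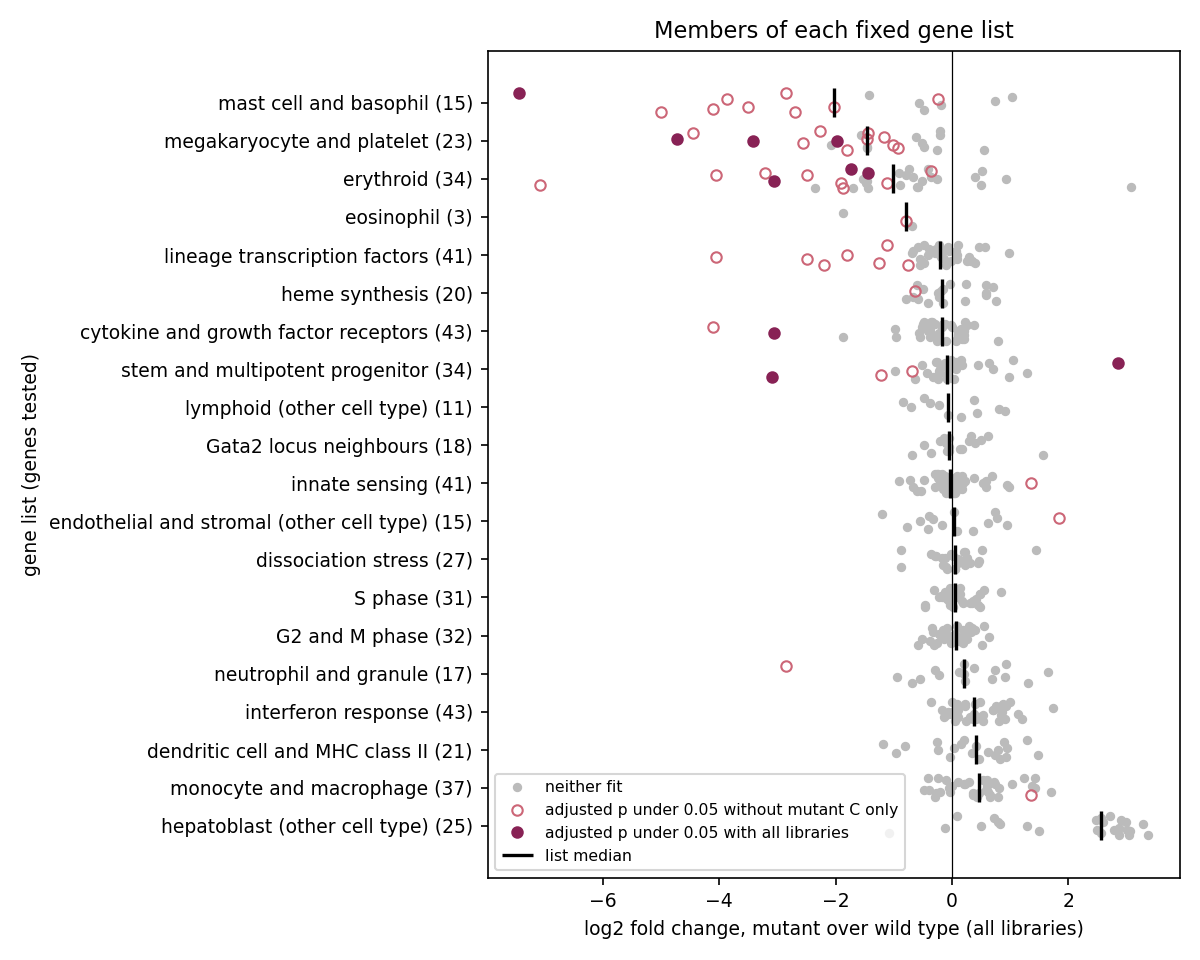
Log2 fold change of mutant over wild type with all 6 libraries (horizontal axis) for each tested member of the 20 gene lists (vertical axis, number tested in brackets); filled dark points passed an adjusted p of 0.05 with all libraries, open points passed without mutant C only, grey points in neither fit, and bars are list medians. The medians run from -2.03 for the mast cell list to 2.57 for the hepatoblast list, and the mast cell, megakaryocyte and erythroid lists lie lowest.

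Among lineage transcription factors, Gata1, Gata2, Klf1 and Zfpm1 were lower in every mutant library than in every wild-type library. Of 41 tested, 0 passed over all genes by edgeR with all libraries, where 9 had an unadjusted p under 0.05. By DESeq2 these 4 passed, and by limma-voom Gata1. Adjusted over the list alone, 4 fell: Gata1, Gata2, Klf1 and Zfpm1. Gata1, the master regulator of erythroid and megakaryocyte differentiation, went from 24.8 ± 4.73 to 1.62 ± 1.09 CPM, 16.7-fold (log2 change -4.06, standard error 0.47, adjusted p = 0.054 over all genes). Klf1, an erythroid activator, was 5.61-fold lower and Zfpm1, the GATA1 cofactor FOG1, 3.49-fold lower. Without mutant C, 7 factors fell over all genes: these 4 and Gfi1b, Ikzf2 and Myb, with log2 changes of -0.86, -0.90 and -0.57. Gata1, Klf1 and Gfi1b are also on the erythroid list and Zfpm1 on the megakaryocyte list, so the lists are not independent. The myeloid factors Spi1, Cebpa and Irf8 had log2 changes of 0.33, 0.09 and 0.29 (standard errors 0.17, 0.16 and 0.18), and none passed over all genes by edgeR in either fit. Irf8 passed adjusted over the list alone without mutant C (log2 change 0.38). Runx1 was 171 ± 2.95 CPM in wild type and 50.5, 164 and 151 CPM in C, D and Q. The list was lower by camera (adjusted p = 3.2e-04), a call lost with an estimated correlation (adjusted p = 0.33).

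**Figure D3:**
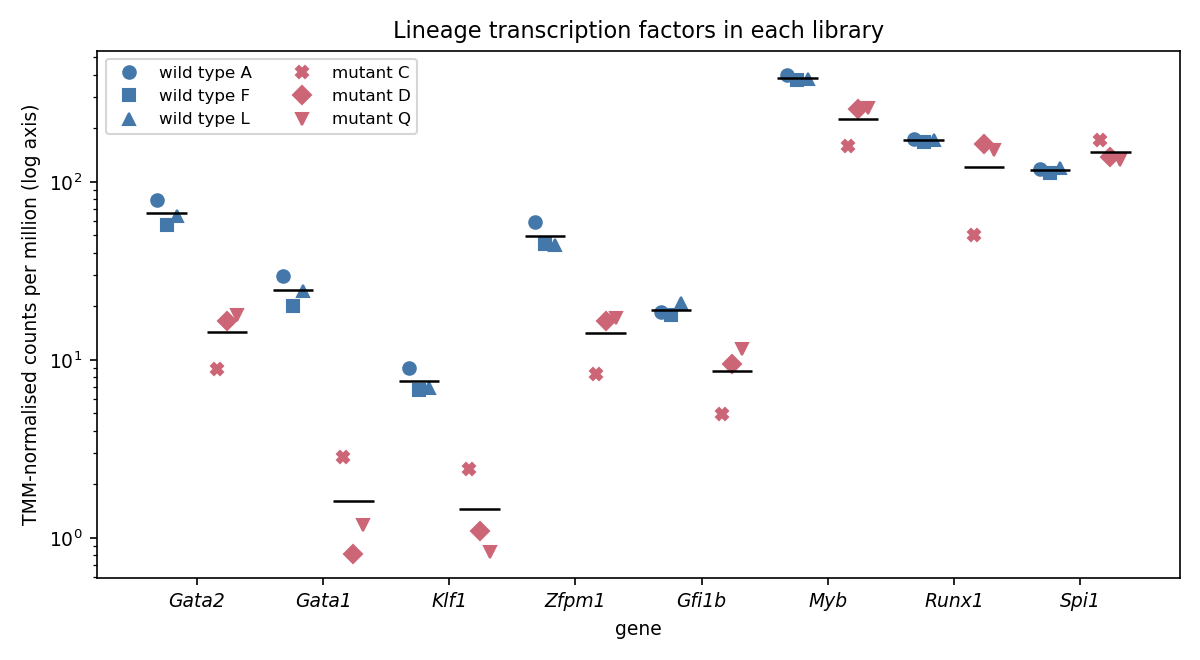
TMM-normalised CPM (vertical axis, log scale) of 8 lineage transcription factor genes (horizontal axis) in each library, blue for wild type and red for mutant, with black bars at the group means (n = 3 each). Gata2 lies between 57.4 and 78.6 in wild type and between 8.92 and 17.8 in the mutant, and Spi1 has no mutant library below the wild-type range.

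Stem and progenitor genes did not move together. Of 34 tested, Slamf1 fell and Socs2 rose over all genes, and both also passed adjusted over the list alone (camera adjusted p = 0.46). Slamf1, which encodes the stem cell marker CD150, went from 3.32 ± 0.431 to 0.403 ± 0.135 CPM, 8.58-fold, at a mean of 35.2 counts. Without mutant C, Meis1, a homeobox gene of early progenitors, also fell over all genes, with a log2 change of -0.51. Of 43 cytokine and growth factor receptor genes, Epor fell over all genes by edgeR with all libraries, and Epor and Il1rl1 without mutant C. By DESeq2 with all libraries Epor, Il1rl1 and Il5ra passed. Adjusted over the list alone, Epor, Il1rl1 and Il5ra fell (camera adjusted p = 0.0092, and 0.57 with an estimated correlation). Epor is also on the erythroid list, Il1rl1 on the mast cell list and Il5ra on the eosinophil list, so these falls are the same genes counted again.

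Granulocyte, monocyte and dendritic cell genes gave no call over all genes by edgeR with all libraries, with 2, 4 and 7 at an unadjusted p under 0.05. DESeq2 and limma-voom each called Hdc alone among them. The monocyte and macrophage list of 37 genes had a median log2 change of 0.47 and was higher by camera (adjusted p = 0.0032), a call lost with an estimated correlation (adjusted p = 0.54) and without mutant C (adjusted p = 0.076, median 0.10). Tyrobp, an immune receptor adaptor gene, shows the part of mutant C: 78.3 ± 14.4 CPM in wild type, 106 and 104 in D and Q, and 555 in C. Clec7a, the receptor gene for fungal beta-glucan, stood at 57.3 ± 6.85 CPM in wild type and 238, 110 and 91.1 CPM in C, D and Q, and rose without mutant C (log2 change 0.81, adjusted p = 0.033). The dendritic cell and MHC class II list of 21 genes was higher by camera (adjusted p = 0.047, and 0.46 with an estimated correlation), with 0 members past the threshold over all genes without mutant C by edgeR (6 at an unadjusted p under 0.05). The list's call ended without mutant C, mutant D, mutant Q, wild type A or wild type L (adjusted p of 0.25, 0.36, 0.051, 0.072 and 0.079). Beside the monocyte and dendritic cell lists, the hepatoblast list had a median of 2.57 (adjusted p = 0.41 with an estimated correlation). The neutrophil list of 17 genes did not differ (median log2 change 0.21, adjusted p = 0.88), and without mutant C it was lower (median -0.19, adjusted p = 0.0047, and 0.51 with an estimated correlation). Its only member past the threshold over the list alone was Hdc, which is also on the mast cell list and fell over all genes without mutant C.

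Interferon response genes were higher by camera, with 36 of 43 tested members above 0 and a median log2 change of 0.39 (adjusted p = 2.8e-04), and adjusted p = 0.45 with an estimated correlation. The hepatoblast list was also higher between these groups (median 2.57, adjusted p = 0.41 with an estimated correlation). None passed over all genes or adjusted over the list alone by edgeR (4 at an unadjusted p under 0.05), and 0 passed by DESeq2 or limma-voom. Without mutant C, 0 of 45 passed over all genes by edgeR (10 at an unadjusted p under 0.05), and Ifit1 rose adjusted over the list alone. Ifit1, an interferon-induced antiviral gene, stood at 0.642 ± 0.197 CPM in wild type and 0.881, 3.25 and 2.17 CPM in C, D and Q. Leaving out mutant D ended the list's call (adjusted p = 0.35). The innate sensing list of 41 genes did not differ as a whole (median -0.03, mean 0.02, camera adjusted p = 0.88). It had 0 members past the threshold by edgeR with all libraries (3 at an unadjusted p under 0.05), 0 by DESeq2 and 0 by limma-voom, and without mutant C Clec7a rose over all genes.

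Genes of other cell types differed between libraries in the hepatoblast list, the liver precursor cells of the tissue from which the progenitors were sorted. Of 25 tested members, 0 passed over all genes by edgeR (15 at an unadjusted p under 0.05) or limma-voom, 9 list members passed by DESeq2, and 12 rose adjusted over the list alone, including Afp, Apoa1, Ttr and Serpina1b. Without mutant C, 0 of 27 passed over all genes by edgeR (20 at an unadjusted p under 0.05), and adjusted over the list alone 16 rose and 1, the apolipoprotein gene Apoe, fell. The median log2 change was 2.57 (camera adjusted p = 1.3e-10, and 0.41 with an estimated correlation). Albumin (Alb) stood at 26.8, 13.3 and 3.32 CPM in A, F and L and at 60.8, 23.2 and 217 CPM in C, D and Q, so the level of mutant D lay within the wild-type range. The most abundant members were Apoe, Mt1 and Dlk1, and Apoe stood at 89.7 ± 22.4 CPM in wild type and at 67.7, 18.5 and 41.3 CPM in C, D and Q. The lymphoid list, led by Cd79b, Nkg7 and Rag2, gave no call in 11 tested genes (camera adjusted p = 0.69), with 0 past the threshold by edgeR over all genes (1 at an unadjusted p under 0.05), DESeq2 or limma-voom, and 0 of 12 by edgeR without mutant C (0 unadjusted). The endothelial and stromal list, led by Pecam1, Eng and Tie1, did not differ as a whole (adjusted p = 0.69), while Col4a1 and Col4a2, which encode basement membrane collagen chains, rose adjusted over the list alone, to 3.59-fold and 1.92-fold of wild type. Col4a1 also rose over all genes without mutant C.

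Lists for dissociation stress, S phase and G2 and M phase gave no call (camera adjusted p of 0.69, 0.35 and 0.69) and held 0 of 27, 31 and 32 tested members past the threshold by edgeR over all genes. They had 0 members past the threshold by DESeq2 and limma-voom, and 2, 0 and 0 at an unadjusted p under 0.05 by edgeR. Without mutant C, 0 of 28, 31 and 32 passed by edgeR, with 2, 2 and 1 at an unadjusted p under 0.05. Pcna, the DNA polymerase clamp gene, was 550.5 ± 69.6 CPM in wild type and 1647, 606 and 691 CPM in C, D and Q, and Mki67 was 939 ± 36.3 CPM in wild type and 288, 844 and 750 CPM in the mutants. The sex-linked genes split the libraries within each genotype. Xist was 4.02 CPM in wild type A and 6.94 CPM in mutant C, against 616 to 888 CPM in the other 4 libraries. Summed Y-linked CPM were 229 and 211 in wild type A and mutant C, and 3.87 to 5.42 in the others. With a covariate for Y-linked expression, 12 genes passed by edgeR, 9 of them among the 19.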

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

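Sample quality weights, the ribosomal protein covariate and the removal of wild type A with mutant C were chosen only after the results were seen; the other tests were planned. All 19 genes past the threshold kept their sign in every alternative, but fewer kept their call. Leave-outs of 1 library aside, 5 of the 19 stayed past the threshold in every setting in which single genes were followed. TPM with pseudocounts of 1 and 0.1 called 10 and 6 of the 19. Of 1536 values for 97 named genes, called or not, 1264 stayed on the same side of the threshold. Another 119 no longer passed, 153 newly passed and 0 called genes reversed. Among genes and lists that were not called, 44 gene signs and 31 list directions changed. The median log2 change of all genes was -0.02 as reported and -0.29, -0.54 and -0.63 with total counts and with TPM at pseudocounts of 1 and 0.1. In the simulations 1% of 2-fold changes were called with all 6 libraries and 72% without mutant C, at the same depths. Each simulation used the dispersions of the matching real fit, so this contrast carries over the spread of those fits and is not separate evidence. The number of changed genes, of lower genes and of genes changed at least 2-fold was 36, 35 and 36 with no filter, 29, 28 and 29 with the stricter filter, and 32, 31 and 32 by limma-voom. DESeq2, on 18406 genes without the edgeR filter, gave 124 genes, 26 higher, 98 lower and 119 at least 2-fold. TPM with a pseudocount of 1 gave 0 higher genes by limma (339 genes at an unadjusted p under 0.05), and with 0.1 it gave 12 genes, 0 higher and 12 at least 2-fold (257 unadjusted). An adjusted p under 0.01 left 0 genes by edgeR, 0 higher, 0 lower and 0 at least 2-fold (587 unadjusted). The Y-linked covariate gave 12, 11 lower and 12 at least 2-fold. Quality weights gave 357 genes, 80 higher, 277 lower and 174 at least 2-fold, the ribosomal protein covariate 81, 9, 72 and 69, and the removal of wild type A with mutant C 131, 17, 114 and 88. The quality weight was 0.043 for mutant C and 0.64 to 3.45 for the others. The ribosomal protein share was 20.9% in mutant C and 6.38% to 8.69% in the others. These settings each reduce the part of mutant C, so their calls are not independent of leaving that library out. Leaving out 1 library gave 0 to 106 genes, 0 to 10 higher, 0 to 96 lower and 0 to 79 at least 2-fold. The log2 change of Gata2 passed the threshold with no filter (-2.19), by DESeq2 (-2.17), with quality weights (-1.84), with the ribosomal protein covariate (-1.81) and without wild type A and mutant C (-1.82), and ran from -2.38 to -1.97 with 1 library left out. The number of lists past the threshold was 2 with an estimated correlation and 4 by fry. With an estimated correlation the adjusted p was 0.091 for the erythroid list, 0.196 eosinophil, 0.542 monocyte, 0.463 dendritic cell, 0.449 interferon, 0.567 receptors, 0.329 transcription factors and 0.408 hepatoblast. By fry, which tests a list against no change and not against other genes, it was 0.452 monocyte, 0.322 dendritic cell, 0.265 for the interferon, receptor and hepatoblast lists, and 0.0783 transcription factors. With no filter it was 0.109 eosinophil and 0.0526 dendritic cell, with the stricter filter 0.486 dendritic cell, and with RLE factors 0.0599 dendritic cell. With the ribosomal protein covariate it was 6.4e-08 heme synthesis, 4.6e-04 neutrophil (reversed to lower), 0.532 for the monocyte, dendritic cell and receptor lists, and 0.0358 endothelial. With quality weights it was 1.1e-06 heme synthesis, 0.555 monocyte, 0.350 dendritic cell and 0.169 receptors. Without wild type A and mutant C it was 9.3e-06 heme synthesis, 0.00145 neutrophil (reversed to lower), 0.0784 monocyte, 0.447 dendritic cell and 0.0665 receptors. With 1 library left out it ran from 3.5e-06 to 0.620 for heme synthesis, 0.00468 to 0.954 neutrophil (lower without mutant C), 8.9e-05 to 0.0760 monocyte, 0.0326 to 0.358 dendritic cell and 2.9e-08 to 0.354 interferon. The cause was not tested.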

Other observations

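The tests of short transcripts and of another cell type in mutant C, of hepatoblast RNA as dilution, of fewer cells against less RNA, and of the origin and genotype of the hepatoblast signal were chosen only after the result was seen, as was the use of the fit without mutant C. In that fit, 9 genes besides Socs2 rose. Col4a1, a basement membrane collagen gene, rose 4.28-fold from 1.46 ± 0.166 CPM, to 5.59 and 6.91 CPM in D and Q (adjusted p = 0.0073 by edgeR). Lpl, the lipoprotein lipase gene, rose 2.50-fold, Cox4i2, a subunit gene of cytochrome c oxidase, 2.38-fold, Hpgd, which encodes a prostaglandin-inactivating enzyme, 2.15-fold, and Peg10, an imprinted gene, 2.80-fold. Dusp5, a phosphatase gene of the ERK pathway, rose 1.77-fold, the C-type lectin genes Clec7a and Clec12a 1.75-fold and 1.62-fold, and Dock1, an activator gene of Rac, 1.6-fold. With mutant C included, the log2 changes of Cox4i2 and Clec12a were 2.14 and 1.49 in place of 1.25 and 0.70, with 71.7 and 246 CPM in mutant C. In mutant C, outside that fit, Peg10 (2.31 CPM) and Dock1 (10.8 CPM) were not above the wild-type libraries, and none of the 9 passed over all genes with all 6 libraries by edgeR. By DESeq2 with all 6 libraries Col4a1, Lpl, Cox4i2, Hpgd and Dusp5 passed, and Peg10, Clec7a, Clec12a and Dock1 did not.

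Genes outside the lists also fell without mutant C. Kcnj5, a potassium channel gene, stood at 6.85 ± 0.804 CPM in wild type and 0.330, 0 and 0.186 CPM in C, D and Q. Tgfbr3, a coreceptor gene for TGF-beta, stood at 20.2 ± 1.42 CPM in wild type and 2.86, 4.92 and 5.46 CPM in C, D and Q (log2 change -1.96, adjusted p = 0.0011 by edgeR).

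Mutant C stood apart from the other libraries. Embryo sex as the whole cause is argued against: the deviations of wild type A, the other library with low Xist, ran opposite to those of mutant C (Spearman's rho -0.409 across genes, which are not independent). These deviations also trended oppositely with gene length, with rho of 0.247 in wild type A and -0.748 in mutant C. Length was not removed before the comparison, so a smaller part of sex is not excluded. A minority of cells of another type is argued against as the whole cause, since 17.6% of 9638 genes with at least 5 CPM lay 2-fold or more below mutants D and Q. The test cannot exclude such cells beside a trend with gene length. That trend lowers long genes by itself, with a median log2 ratio of -1.32 in the bin of longest genes. Over-representation of short transcripts remains a candidate explanation, with a rho of -0.748 between the ratio of mutant C to D and Q and gene length. What would produce it in the RNA or the library is not known from the labels.

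Erythroid, megakaryocyte and mast cell genes were lower in the mutant, with the erythroid call lost at an adjusted p = 0.091 with an estimated correlation. A gene length trend is argued against as the whole cause, since the median log2 change of the 74 genes without mutant C was -1.30 before and -1.32 after the trend was removed. Dilution by hepatoblast RNA would lower genes of all blood cells alike, and TMM scaling takes out such a shared fall. The neutrophil, monocyte and stem cell lists had a median of 0.0321 (interquartile range -0.23 to 0.21) without mutant C. That median alone cannot decide, since TMM would give it with or without dilution. Its contrast with the median of -1.30 for the 74 genes argues against dilution as the cause of their lower level. Fewer cells of these lineages in the gate and less RNA per cell cannot be told apart in bulk RNA, with an interquartile range of 1.59 for the log2 changes. The gate removed cells with CD41, CD48 and TER-119 in both genotypes, and genotype itself remains open.

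Hepatoblast genes were higher in the mutant group by camera, a call lost with an estimated correlation (adjusted p = 0.41 with an estimated correlation). The gate required c-Kit and CD34, and its lineage markers were those of blood cells. Whether it removed all hepatoblasts was not tested. A single source of hepatoblast RNA or cells stays open: over all 25 tested genes the log2 ratio of mutant Q to wild type A had an SD of 1.34 around a median of 2.60, and abundant members such as Apoe, Mt1 and Dlk1, with high levels in wild type, did not share it. Genotype and carry-over that differs between sorts cannot be told apart: 32% of the 25 genes were higher in every mutant library, genes of 1 source move together, and mutant D had a median of -0.14 against the highest wild-type library. Of the 25 genes, 8 had a wild-type mean of at least 5 CPM and 0 were on another list.

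The 10 possible splits of the 6 samples are too few for a share under 0.05. The real split called 19 genes and the highest other 0, with 1 of the 10 splits calling as many. It put 10 lists past the threshold, as did the split of wild type A, wild type L and mutant C from the rest, so 2 of the 10 splits gave as many. Every other split also put lists past the threshold with the preset correlation, from 2 to 10 of them. The number of such calls therefore does not by itself set the genotypes apart from other groupings. With an estimated correlation the real split gave 2 lists and the highest other 0.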
